A study of Mus musculus with 12 samples.

How the data were processed

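RNA was measured in 12 libraries of mouse splenic CD4 T cells, 3 each of KI naive, KIKO naive, KI activated and KIKO activated cells, per the labels. The titles of the KIKO activated samples say T cells without naming CD4, unlike those of the other groups. Activated cells had 16 h of stimulation with beads carrying antibodies to CD3 and CD28. Each library began with 15 ng of total RNA, from which poly(A) RNA was taken and a stranded library made with a TaKaRa SMART-seq kit, per the labels' protocols. Reads were checked with FastQC 0.11.9, trimmed with cutadapt 2.9 and aligned with HISAT2 2.2.0, per the submitters' processing notes. The labels name both GRCm39 and mm10, and the coordinates of the files are GRCm39, which is the build of all coordinates given here. The program that made the values is not given in the sources used here.

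The values used are FPKM as deposited by the authors, 1 file per library. Each line of a file gives the FPKM of 1 transcript event, such as a transcript start, a transcript end, a skipped exon or a retained intron, at a numbered locus. Events at 0 are not listed, so a locus or event absent from a library was taken as 0 there. Duplicate lines of an event were dropped. FPKM give no read numbers, so depth and the sampling error it brings are unknown. The files favour genes with several transcripts. They list 17.0% of 4456 protein-coding genes with 1 transcript in GENCODE M21, 43.2% of 8823 with 2 to 4 and 73.0% of 8645 with 5 or more. A gene missing here is therefore no evidence of silence.

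The level of a locus was computed as the largest of its summed transcript starts, its summed transcript ends and its largest single event. The plan made before the data were examined was to sum FPKM per gene, but events of 1 transcript overlap, so a plain sum would count transcripts repeatedly. At loci of at least 5 FPKM the summed starts lay within 10% of the level at a median of 93.06% of loci per library. KIKO naive 2 had 84.16%. Of 15125 loci, 12918 carried a gene symbol, and where a symbol labelled several loci the one with the highest mean kept it. This left 505 loci without their symbol among the 2207 that have none of their own. Some file names belong to a neighbouring gene. Exon and intron lengths of each locus were compared with GENCODE M21 (GRCm38) genes within 200 kb, lengths only, with no conversion of coordinates. By this, 10278 loci matched their own gene, 694 matched another gene and 2451 were undecided. This check was added after the data were seen. Names from the files are used except for the proteasome loci that match Psmb5, Psmd1, Psmd11, Psme3 and Psmd9, which are named as such. Genes with near-identical copies or pseudogenes, such as Rpl7a, Rps27a, Hnrnpa3, Gapdh and Sub1, may share reads with them and their values are uncertain.

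Values were tested as log2(FPKM + 1) for 9743 loci with an FPKM of at least 1 in at least 3 of the 12 libraries. limma 3.58.1 in R 4.3.3 fitted a mean for each of the 4 groups with an intensity trend (prior degrees of freedom 4), and moderated two-sided tests were adjusted by Benjamini-Hochberg within each comparison, called under 0.05. The 5 comparisons were KIKO against KI in naive cells, KIKO against KI in activated cells, activated against naive in KI and in KIKO cells, and the interaction of genotype and activation. The tests, the filter, the lists and the rule for naming genes were fixed before the data were examined. Of 38 gene lists, 32 had at least 3 tested members. They were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison. A list is said to be called when camera at the preset correlation called it. Camera with an estimated correlation and fry stood beside it. Members are counted with adjustment over all loci and over the list alone.

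Genes were named by rule. For the genotype comparisons and the interaction these were the 12 with the largest change each way, and for activation the 6 each way. All had to pass the test with a mean FPKM of at least 5 in a group and, outside the interaction, no overlap between groups. Predicted genes, pseudogenes and receptor variable segments were left out. Up to 4 members of each list with the smallest p, members that went against their list, all proteasome genes, Cd4, Cd69, Il2ra, Myc, Cdkn1a and Trp53 could be named too. A condition added after the data were seen keeps only top genes whose exon lengths match their own gene. Of the genes allowed, 80 of 181 in the naive comparison, 125 of 190 in the activated one, 61 of 186 for KI activation, 48 of 183 for KIKO activation and 55 of 178 for the interaction were followed, with the 5 matched proteasome loci, under every setting but the minimum log2 fold change of 1. The plan held that setting for named genes too, but it was applied only to the counts of genes called, a departure from the plan. The texts name part of these, and a result left out is not reported here. With 3 against 3 values, the groups fail to overlap by chance in 10% of genes.

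Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, rescaling the libraries to an equal sum, the compared groups alone, no trend, sample quality weights, the replicate number as a block, a minimum log2 fold change of 1, and each library left out in turn. Chosen after seeing the data were summed starts only, the largest event only, names from exon and intron lengths, and a fit without KIKO naive 2 and KIKO activated 3. The fit was tested on simulated data with 200 changed genes among 9743. It recovered 89% of changes of log2 1 in the naive comparison, 82% in the activated one, 85% for KI and 91% for KIKO activation. For the interaction it recovered 66%. In the same order there were 8, 7, 5, 9 and 6 false calls. The changed genes came only from loci with a mean log2(FPKM + 1) over 2, with independent normal noise. For the interaction all simulated changes were positive. Recovery at lower levels, or with as many changed genes as here, was not tested. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.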

Results

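RNA was measured in CD4 T cells from mouse spleen, 12 libraries in 4 groups of 3. The labels name the genotypes only as KI and KIKO. From each genotype 3 libraries came from naive cells and 3 from cells stimulated for 16 h. The stimulus was beads carrying antibodies to CD3 and CD28, which trigger the T cell receptor and a co-stimulatory receptor. The series is concerned with how a faulty proteasome, the complex that degrades ubiquitin-tagged proteins, affects the survival and division of T cells. The question put to the libraries was how KIKO cells differ from KI cells at rest and after stimulation, and whether the 2 genotypes respond alike. The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), so the number of reads behind a value is unknown and no counting interval can be given. The files listed 9771 to 11102 loci per library, and 9743 loci entered the tests. KIKO naive 2 stood apart in this respect, with 85319 listed events against 100188 to 112679 in the other libraries. Fold changes are differences of log2(FPKM + 1) with their standard error, which understates changes of genes at low levels. All adjusted p are two-sided limma tests with Benjamini-Hochberg adjustment over all loci tested, or over all lists for gene lists, n = 3 per group. No label says that the replicates are separate animals, so these p measure only the spread between the samples, which may be technical. The files hold no values of 0, and a 0 given here stands for a gene that a library does not list. That need not mean silence, since Gapdh, a glycolytic enzyme that cells use throughout, was not listed in any of the 6 naive libraries. Each gene named below as rising or falling kept its direction and its side of the threshold under all settings run gene by gene, unless a limit stands beside it. A minimum log2 fold change of 1 was applied to counts only, and named genes with smaller changes would not reach it. Lists are called by limma's camera, and the result of its fry test is given where the 2 differ between genotypes.

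The first principal component held 58.9% of the variance and separated naive from activated libraries. The second held 16.5% and separated the genotypes. The 6 naive libraries lay between -42.41 and -38.88 on the first component, and the KI activated libraries between 47 and 57.07. The KIKO activated libraries lay between these, at 28.46, 40.88 and 11.5. Replicates of a group correlated with Pearson's r of 0.952 to 0.983 across loci.

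**Figure D1:**
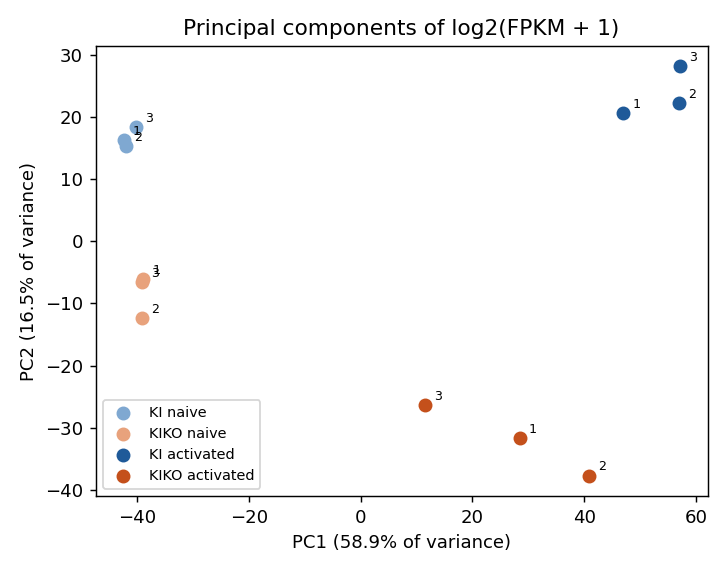
Each point is 1 library on the first 2 principal components of log2(FPKM + 1), with their shares of the variance (58.9% and 16.5%) on the axes and the 4 groups in colour. KIKO activated libraries lay at 28.46, 40.88 and 11.5 on the first component, below the KI activated libraries at 47 to 57.07.

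The altered gene is not given in the sources used here. One locus of the core proteasome separated the genotypes at the level of single exons. Psmb5 encodes the proteasome subunit with chymotrypsin-like activity. The files list its locus under the name Mir686, and the match to Psmb5 was made after the values were seen, from its exon lengths of 229 and 307 bp. The 307-bp exon, at chromosome 14, 54853972 to 54854278 on the minus strand (GRCm39), had an FPKM of 42.8, 42.9 and 43.9 in KI naive libraries and was not listed in any of the 3 KIKO naive libraries. After stimulation it stood at 115, 125 and 141 in KI and at 4.90 and 29.1 in KIKO activated 1 and 2, and was not listed in KIKO activated 3. Over the whole locus the FPKM was 45.6 ± 0.977 in KI naive and 2.49 ± 0.485 in KIKO naive cells (log2 difference -3.75 ± 0.49, adjusted p = 6.9e-04 by limma). In activated cells it was 129 ± 13.1 in KI and 7.99, 35.5 and 4.47 in the KIKO libraries (log2 difference -3.41 ± 0.49, limma adjusted p = 1.9e-04). The 229-bp exon was listed in only 1 KIKO naive library, KIKO naive 3, at 2.95. An exon of 191 bp elsewhere in the locus stood at 1.98 and 2.54 in KIKO naive 1 and 2, was not listed in KIKO naive 3, and stood at 1.26, 1.83 and 2.79 in KI naive libraries. The locus level in KIKO naive 1 and 2 thus came from events that match no Psmb5 exon. The naive log2 difference and the interaction at this locus therefore do not measure Psmb5 alone.

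In naive cells the question was how KIKO cells differ before any stimulus. Genes of the 20S core and the 19S cap of the proteasome were higher in KIKO cells, with few exceptions besides Psmb5. The subunit gene Psma1 rose from 39.2 ± 2.80 to 103 ± 13.0 FPKM (log2 difference 1.37 ± 0.12, adjusted p = 2.5e-05 by limma). Psmd14, whose product removes ubiquitin chains at the proteasome, rose from 17.4 ± 0.966 to 47.5 ± 4.26 (1.39 ± 0.12). Gabarapl1, which codes for a protein of autophagosome membranes, had the largest rise among the named genes, from 3.22 ± 0.377 to 26.1 ± 4.96 (2.67 ± 0.15). Among genes that fell was Khdrbs3, an RNA-binding protein, from 5.10 ± 0.445 to 0.302 ± 0.373 (-2.26 ± 0.23).

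For the 20S core of the proteasome, 13 rose and 0 fell of 13 tested members (13 and 0 adjusted over the list alone) in naive KIKO cells (limma camera adjusted p = 3.2e-13, adjusted p = 0.134 with an estimated correlation). The locus that matches Psmb5 is not among these members under its file name. With it counted, 13 rose and 1 fell of 14. For the 19S cap that recognises ubiquitin chains, 14 rose and 0 fell of 17 tested members (16 and 0 adjusted over the list alone, limma camera adjusted p = 3.9e-19, adjusted p = 0.134 with an estimated correlation). Psmd3 and Psmc5 showed log2 differences of 1.36 ± 0.11 and 1.31 ± 0.11, and Adrm1, a ubiquitin receptor, 1.24 ± 0.09. Psmd8, Psmd13 and Sem1 did not pass, though Psmd8 and Psmd13 did with rescaling to an equal sum, with log2 differences of 0.31 ± 0.09, 0.37 ± 0.11 and 0.31 ± 0.16. The loci that match Psmd1 and Psmd11, listed under the neighbouring names Armc9 and Cdk5r1, rose by 1.53 ± 0.10 and 1.33 ± 0.10. The median log2 difference of the 30 members of both lists was 0.894, and it was 0.823, 0.915 and 1.00 with median-ratio scaling, quantile normalization and rescaling to an equal sum. Among the immunoproteasome and activator genes 1 rose and 1 fell of 6 (1 and 1 adjusted over the list alone), and the list was not called. Psmb8, an inducible catalytic subunit, rose from 24.0 ± 1.30 to 73.4 ± 4.66 (1.57 ± 0.11, adjusted p = 7.9e-06 by limma), while Psmb9 and Psmb10, the other inducible subunits, had log2 differences of -0.38 ± 0.21 and -0.36 ± 0.18 that did not pass.

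**Figure D2:**
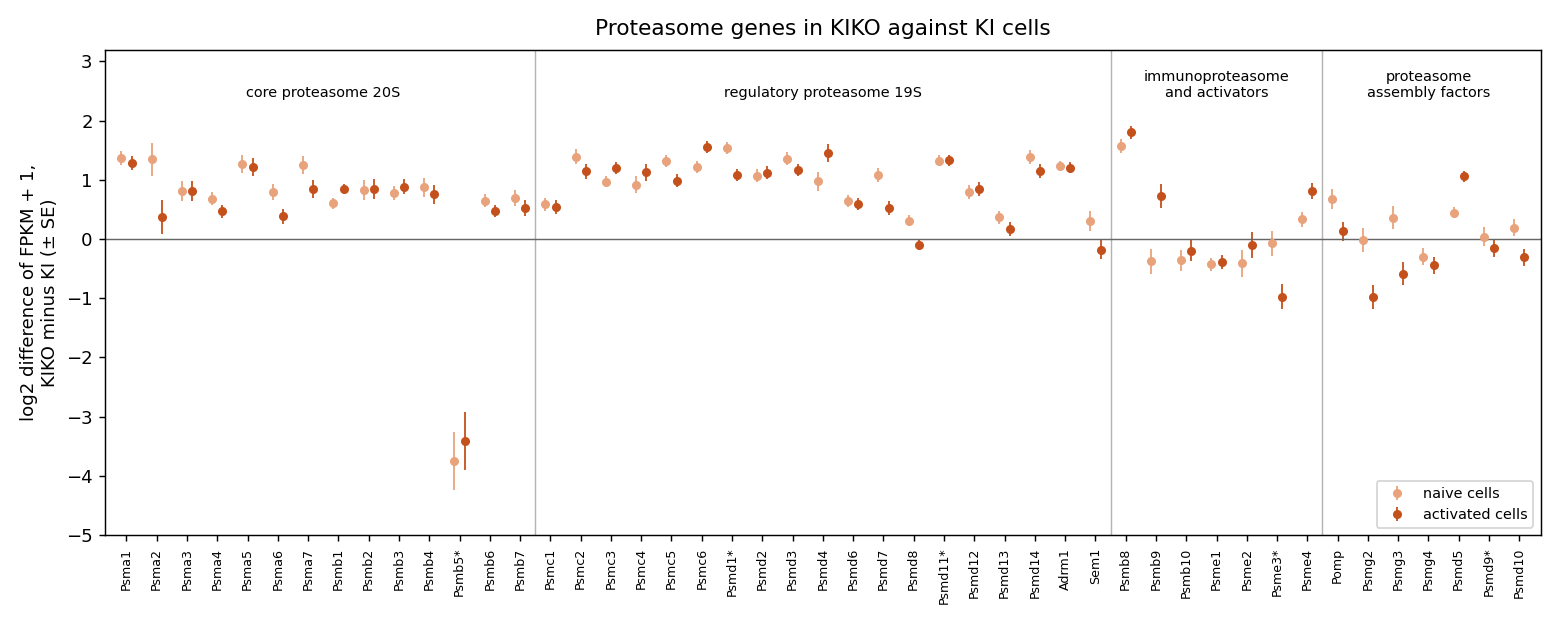
Log2 difference (KIKO minus KI, log2(FPKM + 1) scale) of proteasome genes with bars of 1 standard error, in naive and in activated cells, grouped as 20S, 19S, immunoproteasome and activators, and assembly factors, with asterisks for loci matched under another name. Psmb5 lies at -3.75 and -3.41, and Psma1 at 1.37 and 1.28.

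Of the ubiquitin system and NRF1 pathway, 10 rose and 0 fell of 17 tested members (12 and 0 adjusted over the list alone, limma camera adjusted p = 2.0e-09, adjusted p = 0.134 with an estimated correlation). Vcp, the ATPase that pulls ubiquitin-tagged proteins out of complexes, rose from 72.3 ± 6.46 to 183 ± 9.64 FPKM, and its cofactors Ufd1 and Nploc4 had log2 differences of 1.09 ± 0.10 and 1.03 ± 0.11. Usp14, a ubiquitin protease of the proteasome, rose by 1.12 ± 0.11. Of the autophagy genes, 5 rose and 0 fell of 21 tested members (6 and 0 adjusted over the list alone), a list called by fry (limma fry adjusted p = 0.00364) and not by camera, among them Sqstm1, a receptor for ubiquitin-tagged cargo, from 137 ± 11.5 to 256 ± 25.8. Of the memory and effector genes, 4 rose and 1 fell of 17 tested members (4 and 1 adjusted over the list alone), again a list called by fry (limma fry adjusted p = 0.0437) and not by camera. S100a6, a calcium-binding protein, stood at 0.344, 0 and 0.561 in the KI naive libraries and 4.85, 9.91 and 2.72 in the KIKO naive libraries. Its highest value lay in KIKO naive 2, the library that also held myeloid and NK cell transcripts such as S100a8 (66.0) and Gzma (8.01). Anxa2, which binds membrane lipids, rose from 2.72 ± 0.950 to 12.8 ± 1.08 and Ahnak, a large scaffold protein, from 2.41 ± 0.768 to 13.3 ± 3.30.

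Several T cell lists were called lower in naive KIKO cells. Of the regulatory T cell genes, 1 rose and 4 fell of 11 tested members (1 and 5 adjusted over the list alone, limma camera adjusted p = 7.9e-04, adjusted p = 0.134 with an estimated correlation). Tnfrsf18, a co-stimulatory receptor, fell from 28.9 ± 5.02 to 14.2 ± 1.24, and Lrrc32, which displays latent TGF-beta, stood at 0.977, 2.14 and 1.48 in KI naive libraries and was not listed in any of the 3 KIKO naive libraries. Izumo1r, a folate receptor of regulatory T cells, fell from 12.9 ± 2.00 to 2.24 ± 0.304 (log2 difference -2.10 ± 0.14), but with summed transcript starts only, a setting chosen after seeing the data, its difference was 0.15. Of the T cell activation genes, 2 rose and 5 fell of 24 tested members (2 and 6 adjusted over the list alone, limma camera adjusted p = 0.00315, adjusted p = 0.441 with an estimated correlation, and fry did not call it). For the T cell receptor complex, 0 rose and 3 fell of 13 tested members (0 and 4 adjusted over the list alone, limma camera adjusted p = 0.00166, adjusted p = 0.552 with an estimated correlation, and not called by fry). For cholesterol biosynthesis, 0 rose and 2 fell of 20 tested members (0 and 4 adjusted over the list alone, limma camera adjusted p = 0.00315, adjusted p = 0.763 with an estimated correlation, and not called by fry). The naive T cell program had 1 member that rose and 1 that fell of 19 (1 and 4 adjusted over the list alone, limma camera adjusted p = 0.0364, adjusted p = 0.881 with an estimated correlation, and not called by fry). Prss12, a serine protease, stood at 6.07, 5.32 and 7.84 in the KI naive libraries and was not listed in any KIKO library. Ldha, lactate dehydrogenase, fell from 126 ± 3.60 to 79.1 ± 6.50 and Slfn2, needed for T cell quiescence, from 484 ± 48.6 to 315 ± 30.1. Bbc3, a pro-apoptotic protein under p53 control, rose from 20.3 ± 1.84 to 37.2 ± 1.67 (0.85 ± 0.12, adjusted p = 0.00156 by limma), the only one of 21 p53 target genes that passed.

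In total 1009 of 9743 loci differed between naive KIKO and KI cells at limma's adjusted p, 629 higher and 380 lower. Leaving out KI naive 1, 2 or 3 left 498, 562 and 534. The 62.3% of calls that were higher became 44.2% with median-ratio scaling, 49.4% with quantile normalization and 81.1% with rescaling to an equal sum, which moved the median log2 difference of all loci from 0.047 to 0.143.

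In activated cells the question was how KIKO cells differ after 16 h of stimulation. Rose and fell here mean higher and lower in KIKO than in KI activated cells, not a change on stimulation. Genes of DNA replication were lower in KIKO cells, while targets of p53 and genes of several stress responses were higher. Mcm5, a subunit of the replicative helicase, was at 66.4 ± 21.4 FPKM in KI and 7.76 ± 0.785 in KIKO activated cells (limma adjusted p = 5.5e-07). Cdkn1a, which codes for the cell cycle inhibitor p21, was at 9.50 ± 2.67 in KI and 86.7 ± 31.6 in KIKO (3.03 ± 0.28, adjusted p = 8.9e-06 by limma). Mlkl, the executor of necroptosis, stood at 0, 0 and 0.256 in the KI activated libraries and at 20.1, 26.6 and 18.1 in the KIKO activated libraries. Sqstm1 was at 87.0 ± 11.5 and 461 ± 61.4 (2.39 ± 0.13).

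Of the genes for G1/S and DNA replication, 0 rose and 28 fell of 32 tested members (0 and 29 adjusted over the list alone, limma camera adjusted p = 4.7e-13, adjusted p = 0.175 with an estimated correlation). Mcm3 fell from 125 ± 45.9 to 19.6 ± 1.05, Uhrf1, which carries DNA methylation through replication, by 2.62 on the log2 scale, and Slbp, which binds histone mRNA, from 62.8 ± 6.75 to 24.5 ± 2.72. Tk1, thymidine kinase, stood at 5.15, 9.50 and 7.54 in KI activated libraries and 0.156, 1.28 and 0 in KIKO activated libraries. Ung, a DNA repair glycosylase, and Tipin, a protein of the replication fork, had log2 differences of -2.77 ± 0.25 and -2.47 ± 0.21. Of the G2/M genes 6 fell and 0 rose of 22 (3 and 0 adjusted over the list alone, limma camera adjusted p = 0.0144, adjusted p = 0.175 with an estimated correlation). Of the CDK inhibitors and quiescence genes 6 rose and 1 fell of 12 (6 and 1 adjusted over the list alone), a list called by fry (limma fry adjusted p = 0.00594) and not by camera. Tob1, an antiproliferative protein, rose from 9.77 ± 1.57 to 28.6 ± 2.82 and Klf2, a factor of resting T cells, by 1.02 ± 0.24, while Slfn2 had a difference of -0.82 ± 0.10.

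For p53 targets, 17 rose and 0 fell of 21 tested members (18 and 1 adjusted over the list alone, limma camera adjusted p = 2.8e-09, adjusted p = 0.175 with an estimated correlation). Fas, a death receptor, rose from 12.1 ± 2.40 to 54.6 ± 9.86, Bbc3 from 11.8 ± 2.36 to 41.0 ± 1.94, and Plk2, a stress kinase, from 1.72 ± 0.254 to 25.3 ± 9.38. Polk, a DNA polymerase that bypasses lesions, rose by 1.79 ± 0.15. Among pro-apoptotic genes 6 rose and 3 fell of 17 (6 and 3 adjusted over the list alone), and the list was called by fry (limma fry adjusted p = 1.3e-05) and not by camera. Pmaip1 (NOXA) had a log2 difference of 2.91 ± 0.29 and Apaf1, the platform that activates caspase-9, rose from 4.36 ± 0.933 to 17.0 ± 2.53, whereas Cycs, cytochrome c, fell from 35.3 ± 4.75 to 18.1 ± 2.37. Of the anti-apoptotic genes 3 fell and 0 rose of 10 (3 and 0 adjusted over the list alone), called by neither test, with Bcl2l1 (BCL-XL) falling from 61.1 ± 7.63 to 25.5 ± 6.40.

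Genes of the 20S core and the 19S cap were higher in activated KIKO cells too. Of the 20S core, 12 rose and 0 fell of 13 tested members (12 and 0 adjusted over the list alone, limma camera adjusted p = 6.4e-06, adjusted p = 0.198 with an estimated correlation), and 12 rose and 1 fell of 14 with the locus that matches Psmb5 counted. Of the 19S cap, 14 rose and 0 fell of 17 tested members (14 and 0 adjusted over the list alone, limma camera adjusted p = 6.1e-08, adjusted p = 0.208 with an estimated correlation). Psma1 rose from 98.4 ± 3.22 to 242 ± 34.7, Psmc6 from 58.7 ± 4.04 to 175 ± 23.4 and Psmd4, a ubiquitin receptor, from 247 ± 31.1 to 686 ± 144. Psmb8 rose by 1.80 ± 0.11 and Psme4, a proteasome activator, by 0.81 ± 0.13, and 3 rose and 1 fell of 6 in the immunoproteasome list (3 and 1 adjusted over the list alone), which fry called (limma fry adjusted p = 1.4e-04) and camera did not. The locus that matches the activator Psme3, listed as Aoc3, had a log2 difference of -0.97 ± 0.21. Of the assembly factors 1 rose and 3 fell of 6 (1 and 3 adjusted over the list alone), with Psmd5 at 1.06 ± 0.10 and Psmg2 at -0.98 ± 0.20. Psmd8 and Sem1 had log2 differences of -0.10 ± 0.09 and -0.18 ± 0.16 that did not pass and lay above 0 with quantile normalization (0.078 and 0.014). Of the ubiquitin system, 13 rose and 3 fell of 17 tested members (13 and 3 adjusted over the list alone, limma camera adjusted p = 6.4e-06, adjusted p = 0.178 with an estimated correlation). Zfand5, which stimulates the proteasome, rose from 9.23 ± 1.11 to 40.6 ± 5.15, and Uchl5, a ubiquitin protease of the 19S cap, fell from 35.1 ± 6.69 to 18.7 ± 1.22.

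Among stress responses, the ATF4 list had 12 that rose and 0 that fell of 19 tested members (12 and 0 adjusted over the list alone, limma camera adjusted p = 3.1e-05, adjusted p = 0.261 with an estimated correlation). Trib3, a pseudokinase induced by ATF4, rose from 1.40 ± 0.374 to 19.4 ± 4.90, Sesn2, an inhibitor of mTORC1, from 3.79 ± 1.02 to 38.0 ± 13.2 and Ddit3 (CHOP) from 12.1 ± 1.11 to 34.0 ± 6.74. On stimulation, however, Trib3 fell in KI cells and did not pass in KIKO cells. For the NRF2 oxidative stress response, 11 rose and 0 fell of 14 tested members (12 and 0 adjusted over the list alone, limma camera adjusted p = 4.9e-06, adjusted p = 0.189 with an estimated correlation), with Nqo1, a quinone reductase, at 1.90 ± 0.16 and Gclm, of glutathione synthesis, at 1.85 ± 0.16. For heat shock genes, 11 rose and 1 fell of 17 tested members (11 and 2 adjusted over the list alone, limma camera adjusted p = 0.0016, adjusted p = 0.364 with an estimated correlation), with the co-chaperones Bag3 at 1.96 ± 0.24 and Dnajb1 at 1.45 ± 0.11. Genes of autophagy were higher, and 14 rose and 0 fell of 21 tested members (15 and 0 adjusted over the list alone, limma camera adjusted p = 1.5e-06, adjusted p = 0.147 with an estimated correlation). Gabarapl1 rose from 6.77 ± 0.379 to 70.5 ± 13.8. On stimulation the autophagy list was called lower in KI cells, with 2 that rose and 13 that fell (limma camera adjusted p = 0.0067, adjusted p = 0.235 with an estimated correlation). It was not called in KIKO cells, with 5 that rose and 3 that fell (limma camera adjusted p = 0.625). In the unfolded protein response of the ER, 3 rose and 11 fell of 20 (5 and 12 adjusted over the list alone), and the list was called lower by fry (limma fry adjusted p = 0.00693) and not by camera (limma camera adjusted p = 0.0535). Calr, a chaperone of the ER lumen, fell from 527 ± 10.2 to 271 ± 19.6, and Dnajb9, an ER co-chaperone, rose from 4.68 ± 0.330 to 10.9 ± 1.33.

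Metabolic lists were lower in activated KIKO cells. For ribosome biogenesis, 0 rose and 25 fell of 28 tested members (0 and 25 adjusted over the list alone, limma camera adjusted p = 7.9e-13, adjusted p = 0.178 with an estimated correlation). Dkc1, the pseudouridine synthase of small nucleolar particles, fell from 111 ± 19.9 to 41.2 ± 7.03 and its partner Gar1 from 33.7 ± 3.11 to 13.6 ± 2.51. For cholesterol biosynthesis, 0 rose and 19 fell of 20 tested members (0 and 20 adjusted over the list alone, limma camera adjusted p = 1.8e-11, adjusted p = 0.147 with an estimated correlation), with Idi1, an isomerase of the pathway, falling from 59.9 ± 6.42 to 14.6 ± 3.34. For oxidative phosphorylation, 0 rose and 19 fell of 30 tested members (0 and 21 adjusted over the list alone, limma camera adjusted p = 1.7e-07, adjusted p = 0.175 with an estimated correlation), with Cox5a, a subunit of cytochrome c oxidase, at -0.72 ± 0.12. For glycolysis, 2 rose and 9 fell of 16 tested members (2 and 9 adjusted over the list alone, limma camera adjusted p = 0.00541, adjusted p = 0.264 with an estimated correlation). Ldha fell from 547 ± 76.0 to 133 ± 19.5, and Gpi1, glucose-6-phosphate isomerase, rose from 125 ± 3.41 to 178 ± 11.5.

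Of the T cell activation genes, 2 rose and 16 fell of 24 tested members (2 and 16 adjusted over the list alone, limma camera adjusted p = 2.4e-06, adjusted p = 0.147 with an estimated correlation). Tfrc, the transferrin receptor, fell from 52.3 ± 9.33 to 12.0 ± 2.88, Ccnd2, cyclin D2, from 107 ± 6.96 to 36.7 ± 2.53 and Myc, a transcription factor of cell growth, from 101 ± 16.6 to 35.4 ± 8.34. Cd69, an early activation marker, was at 173 ± 23.1 and 157 ± 42.3 and did not pass (log2 difference -0.17 ± 0.18), and without KIKO activated 3 its difference was 0.048. Of the cytokines and chemokines, 3 fell and 0 rose of 7 (3 and 0 adjusted over the list alone, limma camera adjusted p = 0.0166, adjusted p = 0.211 with an estimated correlation), with Tnfsf11 (RANKL) falling from 8.86 ± 0.401 to 2.25 ± 0.839. The regulatory T cell list had 7 members that fell and 0 that rose of 11 (8 and 0 adjusted over the list alone, limma camera adjusted p = 5.0e-04, adjusted p = 0.147 with an estimated correlation), with Izumo1r at -2.50 ± 0.14. The T cell receptor list had 9 that fell and 0 that rose of 13 (9 and 0 adjusted over the list alone, limma camera adjusted p = 2.3e-04, adjusted p = 0.198 with an estimated correlation). Thy1, a surface protein of T cells, fell from 77.1 ± 8.78 to 18.9 ± 11.0 and Cd3g from 364 ± 27.2 to 178 ± 59.8. NF-kB targets had 4 that fell and 0 that rose of 19 (4 and 0 adjusted over the list alone, limma camera adjusted p = 0.0372, adjusted p = 0.264 with an estimated correlation), among them Rel, an NF-kB subunit, at -0.47 ± 0.12. Of the interferon-stimulated genes, 14 rose and 0 fell of 26 tested members (14 and 0 adjusted over the list alone, limma camera adjusted p = 1.8e-04, adjusted p = 0.198 with an estimated correlation). Ly6a (Sca-1), a surface protein induced by interferon, rose from 5.57 ± 2.58 to 48.6 ± 4.59 and Iigp1, an interferon-induced GTPase, from 0.830 ± 0.583 to 21.5 ± 3.26. On stimulation the interferon list was called lower in KI cells (1 rose and 18 fell). It was not called in KIKO cells (4 rose and 9 fell). The memory and effector list (9 rose and 2 fell of 17, 10 and 2 adjusted over the list alone), the inhibitory receptors (1 rose and 3 fell of 6, 2 and 3 over the list alone) and the naive T cell program (4 rose and 5 fell of 19, 5 and 5 over the list alone) were not called by camera. Of these fry called the memory and effector list higher (limma fry adjusted p = 0.00409) and the inhibitory receptors lower (limma fry adjusted p = 0.0214).

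**Figure D3:**
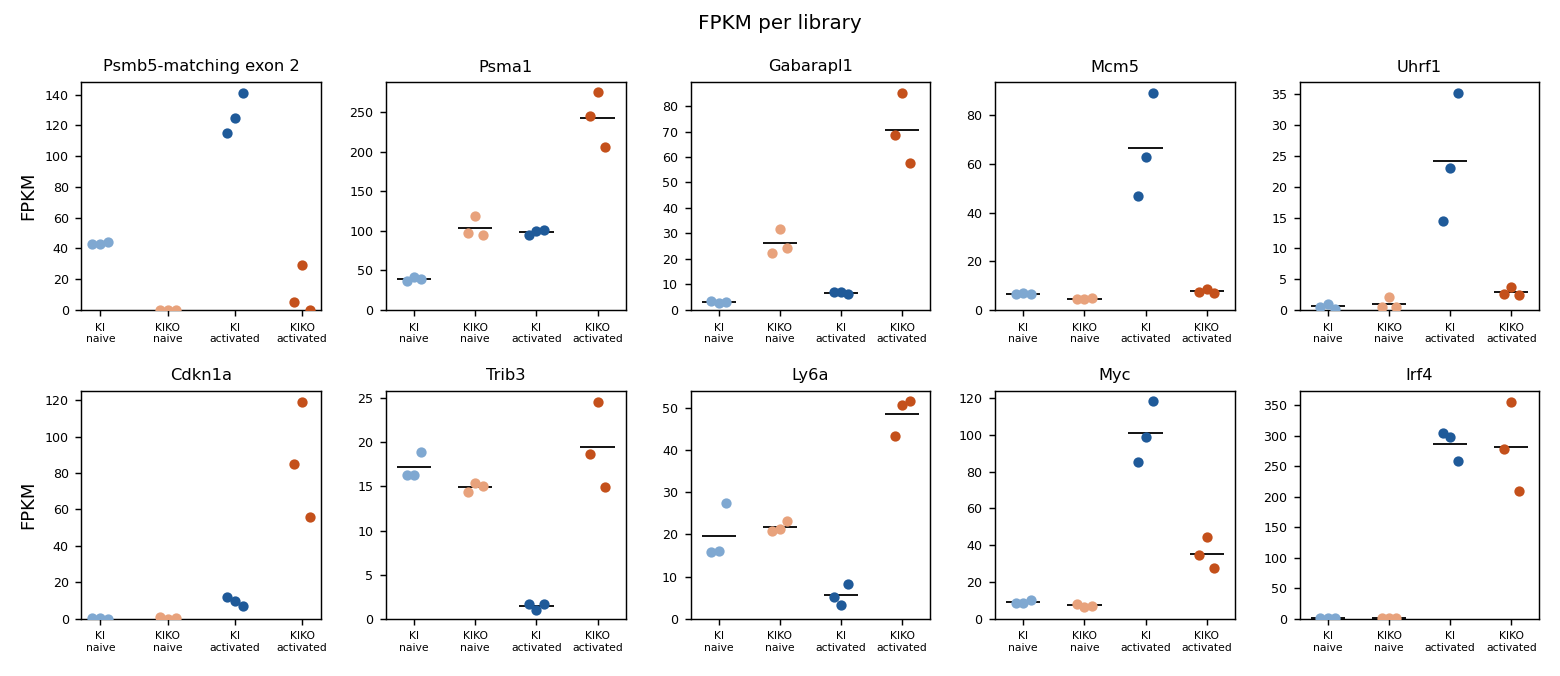
FPKM of the 307-bp exon of the Psmb5 locus and of 9 genes in each library, 1 panel each, with points for libraries in the 4 groups and a line at the group mean for genes without a value of 0. Mcm5 averaged 66.4 in KI and 7.76 in KIKO activated cells, and Cdkn1a 9.50 and 86.7.

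In total 3898 of 9743 loci differed between activated KIKO and KI cells by limma, 2021 higher and 1877 lower. The higher calls made up 51.8%, but 45.4% with median-ratio scaling, 49.1% with quantile normalization and 65.5% with rescaling to an equal sum, which moved the median log2 difference of all loci from 0.04 to 0.168. Which direction holds the majority thus depends on the scaling.

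Stimulation of KI cells, the response against which the KIKO cells were set, raised genes of activation, growth, replication and some stress responses. Irf4, a transcription factor induced by the T cell receptor, rose from 0.611 ± 0.350 to 287 ± 25.6 FPKM (log2 difference 7.50 ± 0.20, adjusted p = 5.9e-10 by limma). Nr4a1, an early response factor, rose by 4.91 ± 0.15 and Cd69 from 5.69 ± 0.698 to 173 ± 23.1. Il2, the main growth factor of T cells, was not listed in any naive library and stood at 11.3, 12.6 and 12.2 in KI activated libraries. Il7r, the receptor of the survival cytokine IL-7, fell from 258 ± 24.0 to 9.72 ± 6.65. For the T cell activation list, 22 rose and 0 fell of 24 tested members (22 and 1 adjusted over the list alone, limma camera adjusted p = 5.8e-13), and it stayed under the threshold with an estimated correlation (adjusted p = 0.0497). Of the G1/S genes, 28 rose and 1 fell of 32 tested members (28 and 1 adjusted over the list alone, limma camera adjusted p = 1.8e-07, adjusted p = 0.241 with an estimated correlation), and Mcm5 rose from 6.56 ± 0.230 to 66.4 ± 21.4. For ribosome biogenesis, 28 rose and 0 fell of 28 tested members (28 and 0 adjusted over the list alone, limma camera adjusted p = 5.2e-13, adjusted p = 0.191 with an estimated correlation), with Nolc1, a nucleolar chaperone, at 2.76 ± 0.16. Proteasome genes rose as well, 13 of 13 in the 20S core, also adjusted over the list alone (limma camera adjusted p = 1.8e-06, adjusted p = 0.191 with an estimated correlation) and 17 of 17 in the 19S cap, also over the list alone (limma camera adjusted p = 5.8e-08, adjusted p = 0.235 with an estimated correlation). Of the stress lists, those of heat shock, ATF4 and the ER were called higher in KI cells, and those of NRF2 and p53 were not. Heat shock genes had 13 that rose and 0 that fell of 17 (13 and 2 adjusted over the list alone, limma camera adjusted p = 2.4e-05, adjusted p = 0.257 with an estimated correlation). The ATF4 list had 13 that rose and 2 that fell of 19 (14 and 2 adjusted over the list alone, limma camera adjusted p = 0.00267, adjusted p = 0.438 with an estimated correlation). The unfolded protein response of the ER had 13 that rose and 3 that fell of 20 (13 and 3 adjusted over the list alone, limma camera adjusted p = 0.00195, adjusted p = 0.241 with an estimated correlation). In the NRF2 list 4 rose and 4 fell of 14 (4 and 4 adjusted over the list alone, limma camera adjusted p = 0.878). Of the p53 targets, 12 rose and 2 fell of 21 tested members (12 and 2 adjusted over the list alone, limma camera adjusted p = 0.0894, limma fry adjusted p = 0.00696), so fry called them and camera did not. Of the interferon-stimulated genes, 1 rose and 18 fell of 26 tested members (1 and 21 adjusted over the list alone, limma camera adjusted p = 1.1e-05, adjusted p = 0.191 with an estimated correlation), and Irf7, their amplifying factor, fell from 11.2 ± 0.568 to 1.00 ± 0.519. Of the naive T cell program, 3 rose and 13 fell of 19 tested members (3 and 13 adjusted over the list alone, limma camera adjusted p = 0.00107, adjusted p = 0.438 with an estimated correlation), with Tcf7, a factor of naive T cells, at -1.86 ± 0.18. In all, 6013 loci changed by limma, 3135 higher and 2878 lower. The higher share of 52.1% became 51.6% with median-ratio scaling, 48.0% with quantile normalization and 44.0% with rescaling to an equal sum, which moved the median from -0.006 to -0.143.

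Stimulation of KIKO cells raised genes of activation, stress responses and growth. Irf4 rose from 1.21 ± 0.383 to 281 ± 73.0 FPKM (log2 difference 6.98 ± 0.20, adjusted p = 1.3e-09 by limma) and Nr4a1 by 5.08 ± 0.15. Il2 was at 9.39, 13.5 and 9.22 in KIKO activated libraries. Cdkn1a stood at 0.708, 0 and 0.501 in KIKO naive libraries and 85.2, 119 and 56.0 in KIKO activated libraries. For the T cell activation list, 22 rose and 1 fell of 24 tested members (22 and 1 adjusted over the list alone, limma camera adjusted p = 8.1e-16), with an adjusted p of 0.0248 with an estimated correlation. Of the p53 targets, 19 rose and 1 fell of 21 tested members (19 and 1 adjusted over the list alone, limma camera adjusted p = 4.0e-10, adjusted p = 0.121 with an estimated correlation), with Phlda3, an inhibitor of AKT, reaching 52.4 ± 14.5. Of the ATF4 list, 17 rose and 0 fell of 19 tested members (17 and 0 adjusted over the list alone, limma camera adjusted p = 4.2e-11, adjusted p = 0.121 with an estimated correlation), among them Slc3a2, an amino acid transporter chain, from 30.2 ± 1.27 to 199 ± 59.5. Of the heat shock genes, 16 rose and 0 fell of 17 tested members (16 and 0 adjusted over the list alone, limma camera adjusted p = 1.2e-11, adjusted p = 0.121 with an estimated correlation), with Hsph1, a chaperone, at 2.89 ± 0.15. Growth lists were called higher in KIKO cells as well. Ribosome biogenesis had 25 that rose and 1 that fell of 28 (25 and 1 adjusted over the list alone, limma camera adjusted p = 9.4e-10, adjusted p = 0.206 with an estimated correlation). Oxidative phosphorylation had 16 that rose and 1 that fell of 30 (16 and 1 adjusted over the list alone, limma camera adjusted p = 3.7e-04, adjusted p = 0.209 with an estimated correlation). Glycolysis had 11 that rose and 1 that fell of 16 (11 and 1 adjusted over the list alone, limma camera adjusted p = 5.2e-04, adjusted p = 0.206 with an estimated correlation). The G1/S list was not called, with 3 that rose and 4 that fell of 32 (2 and 2 adjusted over the list alone, limma camera adjusted p = 0.625). Interferon-stimulated genes were not called either, with 4 that rose and 9 that fell of 26 (4 and 10 adjusted over the list alone, limma camera adjusted p = 0.139). Mcm5 rose from 4.52 ± 0.177 to 7.76 ± 0.785 and Pcna, the replication clamp, by 0.51 ± 0.13, while Cdk2, a kinase of S phase entry, had a difference of -0.53 ± 0.12. In all, 4609 loci changed by limma, 2448 higher and 2161 lower. Their higher share of 53.1% became 53.5% with median-ratio scaling, 49.0% with quantile normalization and 43.5% with rescaling to an equal sum.

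The difference between these responses was tested as an interaction, in which 2010 of 9743 loci passed limma's adjusted p, 876 with a higher and 1134 with a lower response in KIKO cells. The share with a higher response was 43.6%, and 46.0% with median-ratio scaling, 45.7% with rescaling to an equal sum and 49.9% with quantile normalization, where 914 were higher and 918 lower. Trib3 fell on stimulation in KI cells and did not pass in KIKO cells, with a difference of 3.26 ± 0.23, adjusted p = 2.8e-05 by limma. Iigp1 and Irgm1, GTPases induced by interferon, had differences of 3.30 ± 0.37 and 3.00 ± 0.27. Cdca7, a chromatin factor of S phase, and Mcm3 had differences of -3.31 ± 0.31 and -2.49 ± 0.29. The G1/S list had 21 members with a lower and 0 with a higher response of 32 (26 and 0 adjusted over the list alone, limma camera adjusted p = 5.9e-14, adjusted p = 0.179 with an estimated correlation). Ribosome biogenesis had 23 lower of 28 (26 adjusted over the list alone, limma camera adjusted p = 6.7e-15, adjusted p = 0.179 with an estimated correlation). The p53 list had 14 higher of 21 (16 adjusted over the list alone, limma camera adjusted p = 4.8e-11, adjusted p = 0.179 with an estimated correlation) and interferon-stimulated genes had 11 higher of 26 (12 adjusted over the list alone, limma camera adjusted p = 5.0e-07, adjusted p = 0.179 with an estimated correlation). The 20S and 19S lists were not called (limma camera adjusted p = 0.428 and 0.488). The interaction at the Psmb5 locus was 0.34 ± 0.69 and did not pass (adjusted p = 0.774 by limma), and it was -0.46 without KIKO activated 2.

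**Figure D4:**
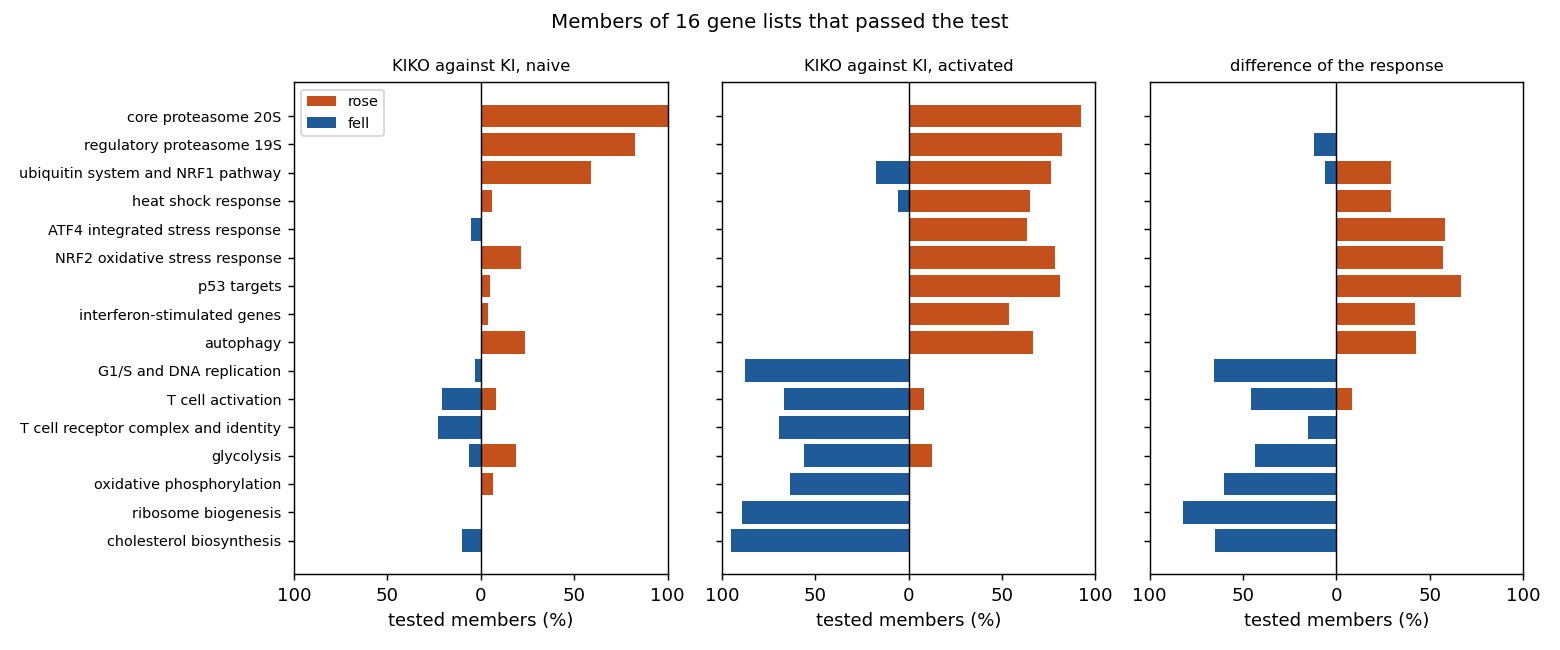
Percentage of the tested members of 16 gene lists that rose or fell at limma's adjusted p, for KIKO against KI in naive cells, in activated cells and for the difference of the response. Bars to the right stand for members that rose and bars to the left for members that fell, such as 28 of the 32 G1/S genes in activated cells.

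Between activated cells the median, the mean and the test differed in sign for the naive T cell program, B cell and CD8 lists, and between naive cells for the immunoproteasome, ER unfolded protein response, G2/M, cytokine, NF-kB and myeloid lists. In KI activation they did so for the NRF2 and anti-apoptotic lists, and in the interaction for the memory and B cell lists, none of which camera called, though fry called the anti-apoptotic list in KI activation (limma fry adjusted p = 0.0282).

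Markers of other cells moved with single libraries. S100a8 and S100a9, proteins of neutrophils and monocytes, stood at 66.0 and 110.2 in KIKO naive 2 and at 45.4 and 92.8 in KIKO activated 2. In the other 10 libraries S100a8 reached at most 1.31 and S100a9 at most 3.69. These genes, Lyz2 and Gzma were singled out after their values were seen. Lyz2, lysozyme of myeloid cells, stood at 26.1 and 22.2 in the same libraries and Gzma, a granzyme of NK cells, at 8.01 and 7.57, and Gzma was not listed elsewhere. Without KIKO naive 2, 692 loci differed between naive cells, and without KIKO activated 2, 3711 between activated cells. Ighm, the heavy chain of IgM, was at 106 ± 5.96 in KI and 41.1 ± 11.4 in KIKO activated cells (-1.38 ± 0.17) beside the lower T cell receptor genes. The other listed B cell markers were low in every library, with at most 4.50 for H2-Eb1 and 2.66 for Cd79a and Igkc. Ighm therefore cannot be read as a measure of B cells here. Cd8b1, a chain of the CD8 co-receptor, was at 7.34 ± 0.803 and 13.7 ± 2.01 in naive KI and KIKO cells (0.82 ± 0.12, adjusted p = 0.00216 by limma). Cd8a, its other chain, reached at most 0.591 in any library. Cd7, a surface protein of T and NK cells, was at 2.81 ± 0.750 in KI and 27.6 ± 8.53 in KIKO activated cells. The B cell list (1 rose and 1 fell of 3, 1 and 1 adjusted over the list alone), the myeloid list (0 and 0 of 5, 0 and 0 over the list alone) and the CD8 list (1 and 1 of 4, 1 and 2 over the list alone) were not called by camera between activated cells, nor between naive cells (0 and 0, 0 and 1, and 2 and 0). fry called the myeloid list higher in activated KIKO cells (limma fry adjusted p = 0.0253) and the CD8 list higher in naive KIKO cells (limma fry adjusted p = 0.0146). Plasma cell, dendritic cell, NK cell, gamma-delta T cell, and erythroid and platelet markers had under 3 members past the filter and were not tested as lists, and no mitochondrially encoded transcript was listed. Genes for haemoglobin and platelets reached at most 1.52.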

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

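Of the tests below, the 2 on the proteasome genes and the 2 on the weaker rise in KIKO cells were written after the results were seen. Those on retained introns and on other splits of the libraries were written before their own results. The tests on retained introns name the higher share in KIKO files and KIKO naive 2, so these were known by then. No splice measure was planned, and the permutation p of the file-wide share is not a test fixed in advance.

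The genotypes differ in their response to activation by a test of that difference, the limma interaction, which called 2010 genes and 15 gene lists. None of the 15 lists keeps its call with an estimated correlation (lowest limma camera adjusted p = 0.179). All values that follow are differences of the log2(FPKM + 1) response, KIKO minus KI. Plk2, Fosl1, Zfp385a, Srxn1, Cdkn1a, Dtl, Tk1 and Fignl1 are not listed in some naive libraries, so their values are not folds. The largest positive differences were Plk2 3.52, Fosl1 3.31, Iigp1 3.30, Trib3 3.26, Zfp385a 3.17, Crip2 3.11, Irgm1 3.00, Gtse1 2.97, Ly6a 2.81, Srxn1 2.79, Zfp365 2.77 and Cdkn1a 2.75. The largest negative ones were Shmt1 -3.35, Cdca7 -3.31, Hells -3.10, Uhrf1 -2.93, Lta -2.84, Dtl -2.82, Ung -2.61, Tk1 -2.59, Mcm3 -2.49, Sub1 -2.45, Mcm5 -2.44 and Fignl1 -2.43. Among proteasome and ubiquitin genes the differences were Psmd7 -0.56, Psmd8 -0.41, Psmg2 -0.97, Psmg3 -0.95, Psmb9 1.10, Psmd5 0.61, Psme3 -0.90, Psmd1 -0.44 and Uchl5 -0.98, with Sqstm1 at 1.496. Among genes of stress and cell death they were Bag3 2.42, Sesn2 2.74, Nqo1 1.86, Fas 2.08, Bcl2l11 1.43, Bcl2l1 -1.46 and Ulk1 1.13. Among genes of T cells and of quiescence they were Tob1 1.40, Klf2 1.23, Batf -1.22, Tfrc -2.17, Cd44 1.24, Fosl2 1.08, Cd69 -0.92, Myc -1.20 and Cd7 2.67. Among genes of metabolism and ribosomes they were Ldha -1.36, Ndufb8 -1.14, Nop16 -1.63 and Idi1 -1.65.

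Some of these calls end under another setting. With a pseudocount of 0.1 Cdkn1a has a limma adjusted p of 0.144. Lta becomes 0.51 with summed starts only, and Ulk1, Nop16, Cd44, Psmg2 and Psme3 no longer pass there. Cd44 is at 0.75 there, with a limma adjusted p of 0.482. Without KIKO naive 2 and KIKO activated 3, Sub1 has a limma adjusted p of 0.0635, and with quantile normalization Fosl2 has a limma adjusted p of 0.0973. Single libraries end others, with highest limma adjusted p of 0.0917 for Psmd7, 0.0849 for Psmg2, 0.0764 for Psmg3, 0.0697 for Klf2 and 0.119 for Psme3 (without KI activated 3), 0.0564 for Psmb9 and 0.059 for Cd69 (without KI activated 2), 0.108 for Psmd8 (without KI naive 2), 0.106 for Psmd1 (without KI naive 1) and 0.0786 for Cd44 (without KIKO activated 1).

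The first pattern weighed is the higher level of proteasome genes in KIKO cells. If scaling of the libraries caused it, the median difference of the 30 tested 20S and 19S genes would shrink under another scaling. The lowest such median over 3 scalings and both states was 0.785. This test could hardly fail, since the median-ratio factors of the libraries ran only from 0.961 to 1.042. A scaling factor would shift all loci alike, and their median difference was 0.047 in naive and 0.04 in activated cells. The 30 genes had medians of 0.894 and 0.846, so they were higher relative to the typical locus. If naive KIKO preparations held activated cells, genes raised by activation in KI at least as much as proteasome genes would be higher in naive KIKO cells. The median of these 901 genes was 0.092, which argues against activated cells as the cause. A response of the cells to reduced Psmb5 could produce the pattern, but the libraries hold no test of that order of events.

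The second pattern is the weaker rise, in KIKO cells, of genes that stimulation raised in KI cells. Of 264 genes raised there by at least log2 2 to at least 10 FPKM, the median KIKO rise was 37.5% of the KI rise. These genes were picked by their KI rise, which favours a smaller part in KIKO cells. Over all loci the interaction called both directions, 876 higher and 1134 lower. If a share of the cells had not been activated, the raised genes would lie near a mixture of activated KI and naive KIKO levels. Of 228 such genes, 23.2% lay over 1.5-fold from the fitted mixture on the same side in all 3 libraries, just past the bound of 20% set for arguing against this as the whole cause, such as Irf4 and Il2 above and Mcm5 and Tfrc below it. This test replaced an earlier one, in which 11.4% of 264 genes reached 0.9 of the KI rise, a value between its bounds, and it was chosen after that value was known, so a partial contribution of cells that were not activated remains open. Without KIKO activated 3, the library nearest the naive ones, 1719 genes were called, 779 with a higher and 940 with a lower response. This count holds both directions, so it cannot tell whether the weaker rise rests on that library. The shares fitted over the 228 genes were 39.1%, 47.2% and 25.8% in KIKO activated 1, 2 and 3. They are medians over genes of the FPKM level between naive KIKO and activated KI cells. They are not shares of activated cells. The weaker rise of these genes was thus lowest in KIKO activated 3 but not confined to it.

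The third pattern lies in the shares of splice events, which the comparisons do not test, although such events can set the level of a locus. Retained introns held 11.7 to 13.85% of the intron-event FPKM in KI files and 14.99 to 15.83% in KIKO files, a mean difference of 2.605 percentage points (exact permutation p = 0.005, two-sided, 400 assignments, the smallest possible). Over 1322 introns measured in all 12 libraries the mean difference was 2.205 percentage points, and the smaller of the naive and activated differences was 1.984. Measured means that the retained and spliced events of an intron summed to at least 5 FPKM in every library. The difference held over the same loci, which argues against other loci being listed as the cause. A retained event that a library did not list was counted as 0, so unequal listing of events within these loci could still contribute. All KIKO files but KIKO naive 2 listed more events (109377 to 112679) than any KI file (100188 to 107385). Without KIKO naive 2 the naive difference was 2.08, which argues against that library. Unspliced RNA would raise most introns. The share of introns higher in KIKO was 58.4% in naive and 63.9% in activated cells. Introns with equal means, 8.8% and 11.3%, were counted as not higher. The lower share lay between its bounds, so the test cannot tell.

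Skipped exons differed by less. Over 6240 exons measured in all 12 libraries the mean difference, KIKO minus KI, was 0.295 percentage points (exact permutation p = 0.015, two-sided), with 0.442 in naive cells and 0.148 in activated cells, where the groups overlap.

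Other splits of the libraries were tried for each count of called genes. For KIKO against KI in naive and in activated cells and for activation in KI and in KIKO cells, 1 of 10 splits gave as many as the real one (1009, 3898, 6013 and 4609 genes), the real one itself, with at most 2 in any other, and 10 are too few to exclude chance. For the interaction 5 of 100 splits gave as many as the real 2010, the highest other 2081. The 4 others as large are among the 7 that kept activated libraries parted by genotype and mixed the naive ones (1347 to 2081). They carry the genotype difference of activated cells and are no chance groups, so the share of 5 in 100 does not decide whether chance is excluded. The 7 that mixed only the activated libraries gave at most 6 and the 85 that mixed both states at most 2.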

How the results depend on the processing

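Of 7683 values of the genes followed under 25 settings, 7262 kept direction and side of the threshold, 343 lost the call, 48 gained one and 30 reversed. Of 435 values of lists under 5 settings, 341 stayed, 88 lost and 6 gained a call. The causes were not tested unless given. Lists called with an estimated correlation numbered 0 in naive and 0 in activated comparisons, 1 in KI and 1 in KIKO activation and 0 in the interaction. Sample quality weights gave 1678 naive, 6600 activated and 3982 interaction calls, but the weights (0.234 to 15.966) did not converge. A minimum log2 fold change of 1, stricter by construction, gave 179, 928, 2500, 1338 and 722. Leaving out 1 library, with fewer samples, gave 498 to 744 naive, 3059 to 3711 activated, 5372 to 5757 KI, 3599 to 4663 KIKO and 1361 to 2103 interaction calls. With the replicate block there were 875, 3825, 5939, 4511 and 1849. Correlations of libraries with the same number ran from -0.099 to 0.217, and not every library correlated best with its own number, so the numbers were not used as pairs. A shared origin remains open, since KI naive and KI activated gave 0.085, 0.062 and 0.184, and KIKO naive 2 and KIKO activated 2 share transcripts of other cells.

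These differences reversed. With a pseudocount of 0.1 the interaction of Il2ra became 0.90, and with rescaling to an equal sum it was 0.12. Psmd8 in activated cells was 0.078 with quantile normalization and 0.036 with rescaling to an equal sum, and Sem1 0.014 with quantile normalization. Summed starts only, chosen after seeing the data, gave Cd4 5.18 in naive and 4.50 in activated cells, Izumo1r 0.15 in naive cells, Lta -0.51 in naive cells, -0.51 in KI activation and 0.51 in the interaction, Wdr12 0.005 in activated cells and 0.94 in KIKO activation, and E2f2 0.12 in KI activation. Psmd9 in naive cells was -0.018 with median-ratio scaling, -0.042 with quantile normalization, -0.039 with quality weights and -0.041 without KIKO naive 2 and KIKO activated 3, a fit chosen after seeing the data. With quality weights Psmd9 was 0.18 in activated cells and 0.22 in the interaction, and 0.032 in the interaction without those 2 libraries. Psme3 in naive cells was 0.024 with rescaling to an equal sum. The Psmb5 interaction was -0.041 with quality weights. Cd69 in activated cells was 0.048 without those 2 libraries.

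With 1 library left out, Cd69 in activated cells ran from -0.35 to 0.048, Psme3 in naive cells from -0.17 to 0.072, Psmd9 in naive cells from -0.041 to 0.114, and the Psmb5 interaction from -0.46 to 0.91. Depth is unknown from FPKM, so its limit on genes at low levels cannot be stated. Of naive lists, fry no longer called T cell activation, naive T cell program, T cell receptor and cholesterol lists, and of interaction lists, heat shock. It also called lists that camera did not, such as pro-apoptotic genes in KI activation and in the interaction.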

Other observations

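The comparison of calls between naive and activated cells and the search for events listed in only 1 genotype were both chosen after the files were examined.

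Genes called by genotype in both naive and activated cells mostly differed the same way. The comparisons share no library, but they come from the same fit, which pooled each gene's variance over all groups. Of 9743 loci, 338 were higher in KIKO in both, against 130.5 for independent lists, and 186 lower in both, against 73.2. Opposite directions were rarer, with 41 higher in naive and lower in activated cells, against 121.2, and 19 the other way, against 78.8. A gene with a small pooled variance is called more easily in both comparisons. The numbers for independent lists are therefore no strict baseline, and how far the shared calls exceed chance was not tested. The pooled variance favours neither direction, and among loci called in both the same direction was the more frequent.

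One transcript-start exon at the locus named Cd4 (chromosome 6, 124877429 to 124877702, minus strand, GRCm39) was not listed in any of the 6 KI libraries. It had an FPKM of 34.1, 31.9 and 40.4 in KIKO naive and 25.7, 20.2 and 19.6 in KIKO activated libraries. Cd4 was not absent from KI cells, where the locus as a whole stood at 203 ± 17.4 in naive and 178 ± 6.34 in activated cells, against 154 ± 17.3 and 107 ± 27.3 in KIKO cells (log2 differences -0.40 ± 0.15, adjusted p = 0.117, and -0.76 ± 0.15, adjusted p = 0.00175, by limma). With summed starts only these differences become 5.182 and 4.504. The start exon above stood well below the level of the whole locus in KIKO cells, so it is not the start of most Cd4 RNA there. A skipped-exon event of Chd3 (chromosome 11, 69251371 to 69251601) stood at 30.5, 9.24 and 30.9 in KIKO naive and 14.5, 14.8 and 9.44 in KIKO activated libraries and was not listed in KI. Of 185211 events, these 2 were the only ones of at least 5 FPKM in all KIKO libraries and in no KI library, and 0 showed the opposite. Activated against naive libraries gave 19 events in activated libraries only and 0 in naive libraries only, and each division by neither genotype nor activation gave at most 12.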
